A study of Homo sapiens with 6 samples.

How the data were processed

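RNA of H9 human embryonic stem cells was profiled on day 0 and day 30 of differentiation into arcuate neurons, with 3 libraries per day. Per the labels' protocols, cells were differentiated in serum replacement and then N2 medium with sonic hedgehog, purmorphamine, SB431542 and LDN-193189, and later with B-27 and DAPT. Total RNA was extracted with TRIzol, depleted of ribosomal RNA, made into libraries with an Illumina TruSeq stranded total RNA kit and sequenced on a NovaSeq instrument, per the labels' protocols. FastQC 0.11.9 and the genome build hg38 are named per the submitters' processing notes. The aligner, the counting program, the annotation release and the strand setting of the counting are not given in the sources used here.

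The deposited values are expected counts, that is, read counts per gene that hold fractions of reads. Whether reads were split between overlapping genes or between several matching places of the genome is not given in the sources used here. The overlapping genes WDR74 and RNU2-2P carried the same fractions in every library, so some reads were counted in both. This unit was read from the values: 92.6% of all values and 83.7% of values above 0 are whole numbers, and the others are mainly simple fractions. The plan assumed raw counts. The values were rounded to whole numbers for the tests instead, and no other normalization by the authors was found in them. The table holds 61853 entries, of which 23900 had no reads in any library. A symbol was found for 42054 of them, and 58298 (94.3%) had a type, position and exon length in GENCODE release 29 of the same build. Entries with no symbol held 4.35% to 5.72% of counts. Columns of values not used numbered 0.

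Total counts were 7758817, 7178453 and 8794008 on day 0 and 9688839, 12924842 and 5013643 on day 30. Mitochondrial genes held 1.91% ± 0.05 of counts on day 0 and 1.76% ± 0.13 on day 30 (SD, n = 3, exact permutation p = 0.2), the signal recognition particle RNA and 7SK RNA 9.06% ± 0.77 and 11.14% ± 1.94 (exact permutation p = 0.2), and the 10 most abundant genes of a library 13.4% ± 1.08 and 15.5% ± 1.54 (exact permutation p = 0.2). A group with no reads was given a floor of 3 counts over the group, against which a fold is a lower bound. Ratios with 1 to 3 counts in a group have a 95% counting interval, which assumes independent reads.

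Differential expression was tested in R 4.3.3 with edgeR 4.0.16, by the quasi-likelihood test with TMM normalization after filterByExpr, which left 18040 genes. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Tests are 2-sided. The biological coefficient of variation was 0.153. Values are given as CPM, means with the SD of 3 libraries, and as log2 fold changes of day 30 against day 0 with their standard error. For edgeR values this standard error is approximate, as the absolute log2 fold change divided by the square root of the test's F statistic. Gene sets were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01 between genes, and again with the correlation estimated for each list, and with fry. Adjusted p-values of lists are over all lists tested.

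The tests, the alternatives, the rule for named genes and 33 gene lists with 635 members were chosen before the data were examined. The pre-rRNA processing lists were UtpA, UtpB, U3 snoRNP proteins, the Mpp10 module, other small subunit processome factors, late 40S maturation, large subunit assembly, the RNA exosome and cofactors, RNase MRP proteins and exonucleases, H/ACA snoRNP proteins, RNA polymerase I, abundant nucleolar proteins, and processing snoRNAs with RMRP. The first 12 of these, which hold proteins, made up the 188 processing factors. The other lists were snoRNA host transcripts, cytosolic and mitochondrial ribosomal proteins, the MYC family, pluripotency, cell cycle, pan-neuronal, hypothalamic and arcuate, neural progenitor, astroglia, oligodendroglia, mesenchymal and neural crest, endoderm, floor plate and sonic hedgehog response, choroid and ependymal, telencephalon, hindbrain and spinal cord HOX genes, endothelial, p53 targets, and the unfolded protein and integrated stress response. The small and large subunit factors were compared by the difference of their mean log2 CPM per library, with an exact permutation test and with fry.

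Named genes were taken by a rule with 3 parts. The first part was a fixed set of genes (POU5F1, NANOG, SOX2, LIN28A, TUBB3, MAP2, STMN2, NKX2-1, POMC, MKI67, MYC, MYCN, FBL, NCL, NPM1, DDX21, URB1, UTP23, UTP4, WDR43, NOL11, DIS3, EXOSC10, MTREX, POLR1A, UBTF, RRN3 and NAT10). The second was the 5 largest rises and 5 largest falls among genes that passed, had CPM ranges that did not overlap and a mean log2 CPM of at least 5. The third was, for each list, the passing member with the largest fall and with the largest rise, and for the processing lists the member nearest to 0 if it did not pass. Genes outside the rule are said to have been chosen after their values were seen, and values of some single genes under the rule are not reported here.

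The steps were tested on simulated data, in which counts for the 18040 tested genes were drawn from the means and sizes of the real libraries. Of these, 200 genes were changed. The filter left 17361 genes, among them 65 changed 1.5-fold, 63 changed 2-fold and 61 changed 4-fold, and the shares recovered are of these. The edgeR step for day 30 against day 0 recovered 12.3% of genes changed 1.5-fold, 57.1% of those changed 2-fold and 96.7% of those changed 4-fold. Of its 107 calls, 3.7% were false. Far fewer genes changed there than in the real data, so the adjusted threshold was stricter in the simulation. Of 200 unchanged lists, 1.5% had p under 0.05 by camera and 6% by fry. Genes were drawn independently there, so these shares do not hold for lists of correlated genes. In the real data the estimated correlation was 0.171 for all factors and 0.686 for cytosolic ribosomal proteins. In the test of the difference between small and large subunit factors, a simulated difference gave −0.56 (exact permutation p = 0.1) and a shift of both lists alike gave 0.09 (exact permutation p = 0.2).

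Alternatives were DESeq2 size factors, upper-quartile normalization, total counts only, mitochondrial and small RNA genes left out, no filter on low counts, a stricter filter of 50 counts in at least 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, each library left out in turn, a test against a 1.5-fold change, at least a 2-fold change, removal of the trend on gene length, and adjustment over the list alone. Subtraction of the reads of small RNA genes that lie in exons of another gene on the same strand was added after seeing the data. No library was left out of the reported comparison. Pre-rRNA itself was not analysed here, as the table holds genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.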

Results

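Gene expression was measured by total RNA sequencing in H9 cells, an established human embryonic stem cell line, and in hypothalamic neurons of the arcuate nucleus type made from them in culture. The 6 libraries fell into a pair of groups by day of differentiation, with 3 libraries from day 0 and 3 from day 30. Total counts were 7758817, 7178453 and 8794008 in the day 0 libraries and 9688839, 12924842 and 5013643 in the day 30 libraries. Across the 18040 genes tested, log2 CPM (counts scaled by library size) of libraries from the same day correlated with a Pearson's r of 0.979 to 0.983 on day 0 and 0.97 to 0.985 on day 30. Libraries from different days correlated with r of 0.594 to 0.614. These are correlations across genes, and genes are not independent replicates. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure the spread between these samples. Floors and counting intervals cover counting error only.

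The comparison of day 30 with day 0 addressed how expression of the pre-rRNA processing factors, the proteins and RNAs that cut, modify and fold the ribosomal RNA precursor in the nucleolus, changed as stem cells were turned into neurons. The RNAs of nearly all of these factors were lower on day 30, relative to the other RNAs of a library. A difference in RNA per cell between the days could not be judged. Protein levels were not measured, and a protein said to fall or rise here stands for its RNA. Of 180 factors tested, 163 fell and 5 rose, and 109 fell by 2-fold or more. The most abundant nucleolar proteins were among them. NPM1 (ENSG00000181163.14, chromosome 5, 171387116 to 171411137, hg38), the nucleolar chaperone nucleophosmin, went from 2060 ± 153 CPM to 242 ± 19.4 CPM (SD, n = 3 per day), a log2 change of −3.09 ± 0.12 (SE). FBL (ENSG00000105202.9, chromosome 19, 39834458 to 39846414), which encodes the box C/D methyltransferase fibrillarin, went from 132 ± 15.5 to 9.74 ± 0.991 CPM, a log2 change of −3.74 ± 0.14.

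The median log2 change of the 180 factors was −1.21, with quartiles of −1.64 and −0.71. The counts were 163 and 5 also when adjusted over the list alone. As a set, the factors fell relative to other genes (camera, 2-sided p = 3.21e-17 with a preset correlation), and p = 0.0656 with an estimated correlation, which does not pass the threshold. With the preset correlation, camera also gave 2.29e-17 for a split of the 6 libraries that mixed the days. The factors also passed fry, which asks whether they move one way on balance without comparing them with other genes. The fall stood in a wide change of expression between the days, as 13827 of the 18040 tested genes (76.6%) passed the edgeR test, 7186 higher and 6641 lower on day 30. Of these, 5361 were higher and 4451 lower by 2-fold or more. The CPM ranges of the groups did not overlap for 14346 genes (79.5%), against 10% by chance for 3 against 3 libraries.

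**Figure D1:**
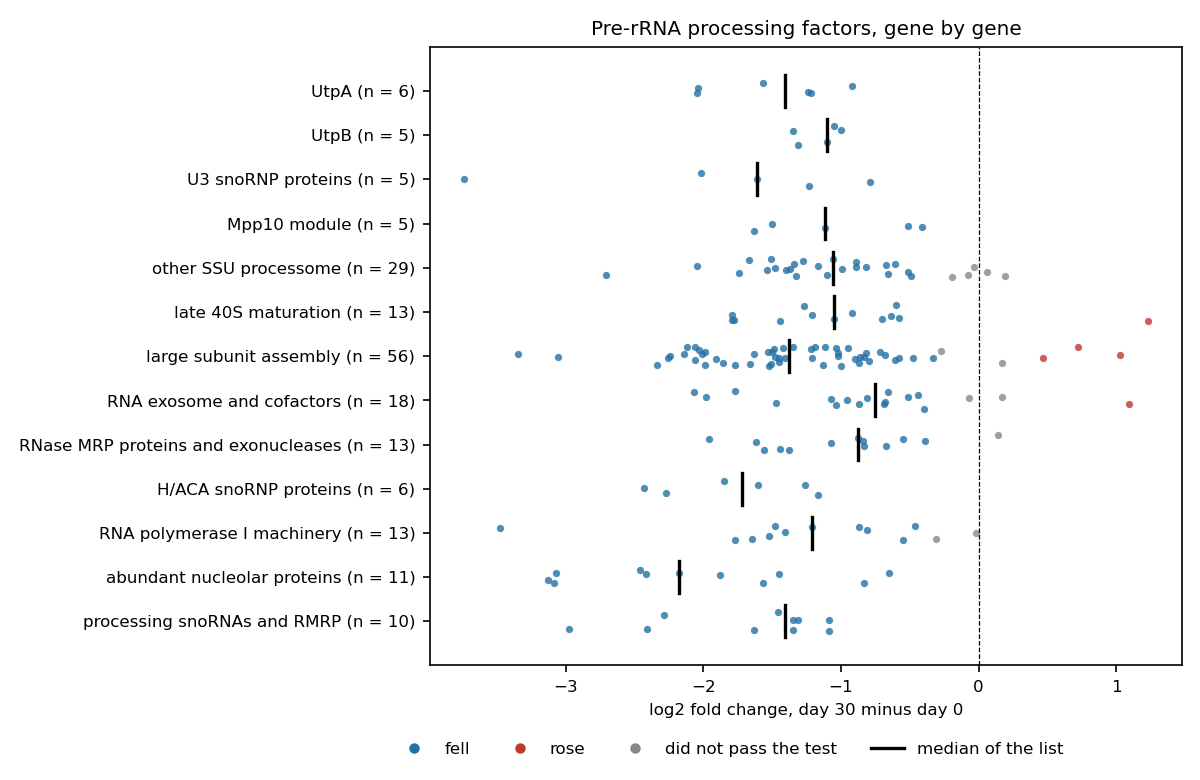
Log2 fold change, day 30 minus day 0, of each tested member of the pre-rRNA processing factor lists, with 1 point per gene, blue for genes that fell, red for genes that rose, grey for genes that did not pass the test, and a black bar at each list's median. Every list's median was below 0, from −0.75 for the RNA exosome to −2.18 for the abundant nucleolar proteins.

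Every tested member of the modules that act first on the precursor fell, with PWP2 of UtpB not tested. All 6 tested UtpA proteins fell, with HEATR1 at a log2 change of −2.05 ± 0.12 (288 ± 29 to 69.6 ± 4.84 CPM), WDR43 at −2.04, NOL11 at −1.57 and UTP4 at −0.92. UtpA is the module that binds the nascent precursor first. The 5 tested UtpB proteins fell, led by WDR36 at −1.35, as did the 5 proteins of the U3 small nucleolar ribonucleoprotein (snoRNP), which include FBL, and the 5 proteins of the Mpp10 module, led by IMP3 at −1.63. The medians of these lists were −1.41 for UtpA, −1.10 for UtpB, −1.61 for the U3 snoRNP and −1.12 for the Mpp10 module. The camera adjusted p was 0.00622, 0.0165, 0.00627 and 0.031 in that order, and the adjusted p with an estimated correlation was 0.243, 0.175, 0.252 and 0.349. With DESeq2 statistics the adjusted p was 0.0532 for UtpB and 0.121 for the Mpp10 module, and over all alternatives it ranged from 7.86e-05 to 0.175 and from 0.00062 to 0.349. For every list of factors the counts were the same when adjusted over the list alone.

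Among the other factors of the small subunit processome, the particle that assembles on the 5′ part of the precursor, 24 of 29 tested fell and none rose. The median was −1.06 (camera adjusted p = 1.57e-05; adjusted p = 0.243 with an estimated correlation). UTP20 went from 194 ± 29.9 to 29.7 ± 3.87 CPM, a log2 change of −2.71 ± 0.15, and the RNA acetyltransferase NAT10 fell by 1.33 on the log2 scale. UTP23, a processome protein, was at 25.3 ± 4.77 CPM on day 0 and 26.4 ± 1.3 CPM on day 30, a log2 value of 0.06 ± 0.16 that did not pass the test (adjusted p = 0.739). Leaving out day 0 replicate 1 put it at −0.11. DDX52, an RNA helicase, had the value nearest to 0 in this list, −0.03 (adjusted p = 0.928), and its sign turned with several alternatives, from −0.19 to 0.24 with 1 library left out.

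Late maturation of the 40S subunit followed the same direction, with 12 of 13 tested factors lower and 1 higher (median −1.05, camera adjusted p = 0.00384; adjusted p = 0.299 with an estimated correlation). NOB1, the endonuclease that makes the 3′ end of 18S rRNA, fell by 1.79 on the log2 scale. The exception was RIOK3 (chromosome 18, 23452823 to 23486603), an atypical kinase that acts on late pre-40S particles, which rose from 36.8 ± 8.27 to 86.3 ± 12.7 CPM, a log2 change of 1.23 ± 0.17 (adjusted p = 6.83e-05).

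Of 56 tested factors of large subunit assembly, 51 fell and 3 rose (median −1.38, camera adjusted p = 1.08e-09; adjusted p = 0.175 with an estimated correlation). TMA16 had the largest fall of the list, from 54.4 to 5.47 CPM, a log2 change of −3.35 ± 0.16, and URB1 went from 116 to 57.4 CPM, a log2 change of −1.02. SBDS and ZNF622, which rose, were chosen after their values were seen. SBDS, which helps release an anti-association factor from the 60S subunit, had a log2 change of 0.72 (adjusted p = 0.00569), but its near-identical pseudogene SBDSP1 rose by 0.87 and reads can pass between them. ZNF622 had 0.47 (adjusted p = 0.0233) and did not pass without day 0 replicate 1, day 0 replicate 2, day 30 replicate 1 or day 30 replicate 2, which left 4 factors higher. The third, WDR74 (chromosome 11, 62832342 to 62841809), was listed at 79 ± 7.75 CPM on day 0 and 161 ± 35.4 CPM on day 30, a log2 change of 1.03 ± 0.16. The U2 small nuclear RNA gene RNU2-2P lies within it on the same strand, at 62841619 to 62841809. With the reads of RNU2-2P subtracted, an alternative chosen after seeing the data, WDR74 was at 49 ± 4.71 and 16.2 ± 1.85 CPM, a log2 change of −1.58 ± 0.14.

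**Figure D2:**
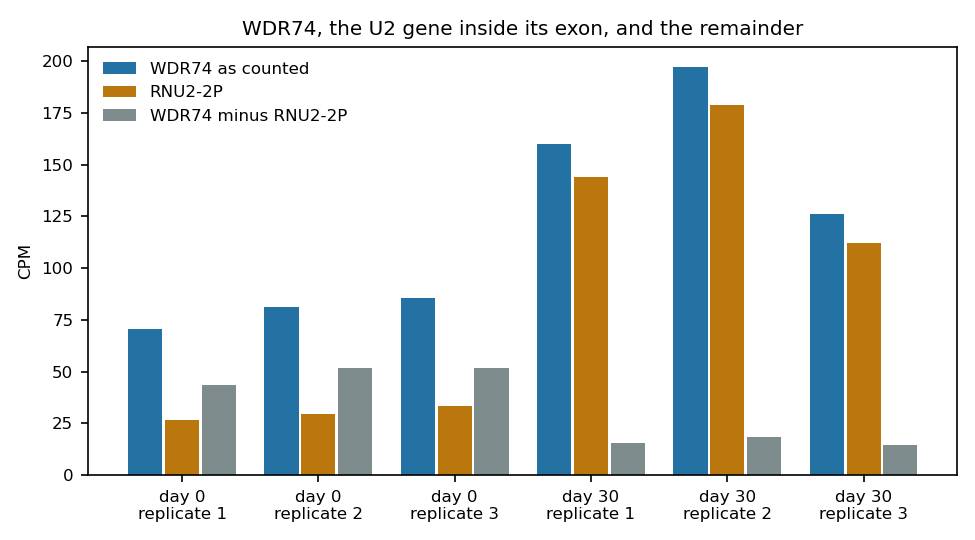
Bars give CPM in each of the 6 libraries for WDR74 as counted, for the U2 small nuclear RNA gene RNU2-2P within it, and for WDR74 minus RNU2-2P. The mean of WDR74 went from 79 to 161 CPM as counted, and from 49 to 16.2 CPM after subtraction, between day 0 and day 30.

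The RNA exosome, the complex of exonucleases that trims the 3′ ends of precursors, and its cofactors had the smallest median among the factor lists, −0.75, with 15 of 18 tested members lower and 1 higher (camera adjusted p = 0.00371; adjusted p = 0.175 with an estimated correlation). EXOSC9 fell by 2.07 on the log2 scale, the helicase MTREX by 1.07 and the nuclear exonuclease EXOSC10 by 0.69. DIS3, another catalytic subunit, had −0.40 ± 0.16 (adjusted p = 0.0413). It did not pass without day 0 replicate 2 (0.102), day 0 replicate 3 (0.117) or day 30 replicate 3 (0.141), with total counts only (0.0746) or with the stricter filter on low counts (0.117), and its adjusted p ranged from 0.0103 to 0.141 over the alternatives. EXOSC6, a subunit of the core ring, rose from 34.4 ± 3.19 to 73.2 ± 1.28 CPM, a log2 change of 1.09 ± 0.11 (adjusted p = 7.5e-06). Among RNase MRP proteins and exonucleases 12 of 13 fell (median −0.88, camera adjusted p = 0.00277; adjusted p = 0.212 with an estimated correlation), with RPP40 lowest at −1.96 ± 0.31. With DESeq2 statistics this list had an adjusted p of 0.0531, and over all alternatives it ranged from 0.000106 to 0.212.

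All 6 H/ACA snoRNP proteins, which carry the pseudouridine-forming enzyme and its assembly factors, fell (median −1.72, camera adjusted p = 0.00574; adjusted p = 0.243 with an estimated correlation), and the assembly factor SHQ1 went from 32.2 to 5.84 CPM. For RNA polymerase I and its transcription factors, 11 of 13 tested members fell (median −1.21, camera adjusted p = 0.00146; adjusted p = 0.212 with an estimated correlation). The subunit POLR1G went from 48 to 4.24 CPM, a log2 change of −3.48 ± 0.17, whereas the largest subunit, POLR1A, fell by 0.55 and the promoter-binding factor UBTF by 0.46. RRN3, which brings polymerase I to the promoter, held 15 counts over the day 0 libraries and 10 over the day 30 libraries and was not tested. All 11 abundant nucleolar proteins fell (median −2.18, camera adjusted p = 7.41e-05; adjusted p = 0.175 with an estimated correlation). Beside NPM1 these included nucleolin (NCL, 1290 ± 146 to 284 ± 27.5 CPM), the helicase DDX21 (522 ± 94.2 to 94.9 ± 8.36 CPM) and NPM3, with the largest fall of the list at −3.13.

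The 12 factors that did not pass had log2 values from −0.31 for TAF1C to 0.19 for C1orf131. The others, named after their values were seen where the rule for named genes does not cover them, were UTP23, UTP25, DDX49, DDX52, DDX51, SPATA5L1, TENT4A, TENT4B, RPP14 and TAF1A. The sign of TAF1A, at −0.02, and of TENT4B, at −0.07, turned with another scaling of the libraries, to 0.07 and 0.02 with total counts only. The other 8 of the 188 listed factors (PWP2, AATF, WDR46, DDX24, RPP21, PARN, POLR1H and RRN3) had at most 10 counts in any library and were not tested. WDR46, RPP21 and POLR1H lie in the MHC region, where most genes held almost no reads.

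**Figure D3:**
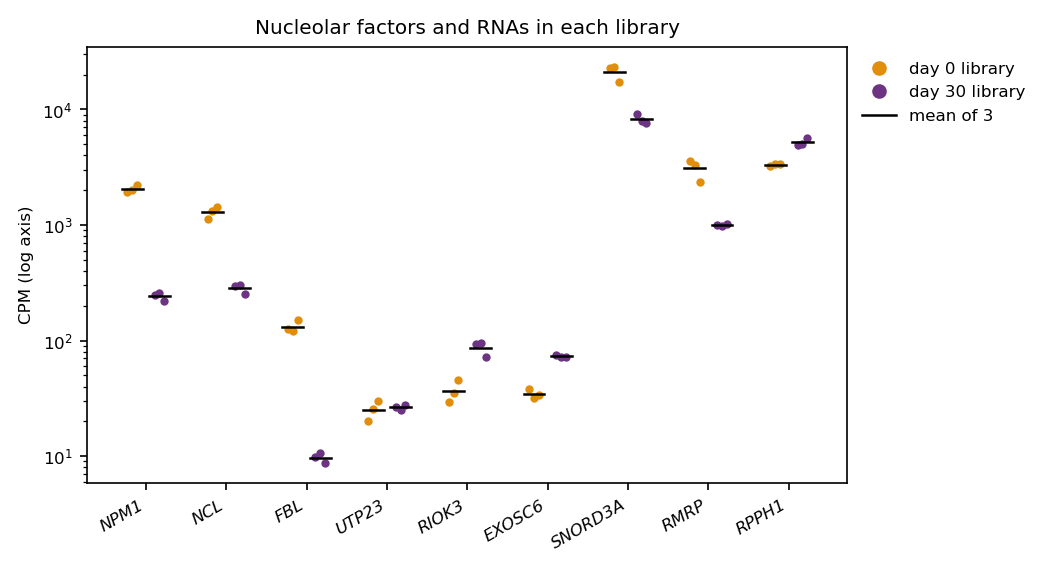
CPM on a log axis in each library for NPM1, NCL, FBL, UTP23, RIOK3, EXOSC6, SNORD3A, RMRP and RPPH1, with 1 point per library and a line at the mean of the 3 libraries of a day. NPM1 went from 2060 to 242 CPM and EXOSC6 from 34.4 to 73.2 CPM, and UTP23 was at 25.3 and 26.4 CPM.

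Both branches of the machinery, the factors of the small and of the large subunit, fell. Of 50 tested small subunit factors, from the UtpA, UtpB, U3 snoRNP, Mpp10 and other processome lists, 45 fell (median −1.19). The mean log2 CPM of small subunit factors minus that of large subunit factors was −0.13 ± 0.01 on day 0 and −0.02 ± 0.05 on day 30 (SD, n = 3), a difference of 0.11 (2-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The fry test of limma did not pass for this difference. That call depended on the setting, as fry passed with no filter on low counts, for a difference of 0.10, and with reads of overlapping small RNA genes subtracted, an alternative chosen after seeing the data, for a difference of 0.16.

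RNAs that guide or catalyse processing fell as well. All 10 tested members of the list of processing snoRNAs and RMRP fell (median −1.41, camera adjusted p = 0.002; adjusted p = 0.175 with an estimated correlation). The adjusted p was 0.0595 with DESeq2 statistics and 0.0763 with the stricter filter on low counts, and over all alternatives it ranged from 3.07e-05 to 0.175. SNORD22 had the largest fall, −2.98, with 147 counts over the day 0 libraries and 23 over the day 30 libraries. The data hold more than 1 entry of this name, and the entry with the most counts was used. SNORD22 lies within its host transcript SNHG1, so the division of reads between them is uncertain. The most abundant, chosen after their values were seen, were SNORD3A, a copy of the U3 RNA needed for the early cleavages, at 21100 ± 3370 CPM on day 0 and 8260 ± 857 CPM on day 30, and RMRP, the RNA of RNase MRP, at 3090 ± 637 and 997 ± 24.1 CPM. U3 has near-identical copies, so the value of a single copy is uncertain. The RNA of RNase P, RPPH1, also chosen after its values were seen, rose from 3340 ± 66.8 to 5200 ± 362 CPM (log2 change 0.64 ± 0.11, adjusted p = 0.000347). Of 16 tested snoRNA host transcripts, from whose introns snoRNAs are cut, 15 fell (median −1.68, camera adjusted p = 1.97e-05; adjusted p = 0.175 with an estimated correlation), and SNHG1 went from 192 to 28.1 CPM. Together, snoRNAs, RMRP and RPPH1 made up 2.85% ± 0.5 of counts on day 0 and 1.54% ± 0.05 on day 30 (n = 3, exact permutation p = 0.1).

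The mRNAs of cytosolic ribosomal proteins had a larger median fall than the processing factors. Of 79 tested, 78 fell and none rose, with a median of −2.46 (camera adjusted p = 9.38e-20; adjusted p = 0.272 with an estimated correlation). RPS6 went from 1020 ± 69.9 to 92.7 ± 10.2 CPM, a log2 change of −3.46 ± 0.13. The exception was RPS9, chosen after its value was seen, at −0.71 (adjusted p = 0.396) with at most 18 counts in a library. RPS18 held no reads and was not tested. As a share of counts, these mRNAs made up 4.68% ± 0.34 on day 0 and 0.97% ± 0.06 on day 30 (n = 3, exact permutation p = 0.1). Of 78 tested mitochondrial ribosomal protein genes, 67 fell and 1 rose, with a median of −1.05 (camera adjusted p = 1.16e-09; adjusted p = 0.272 with an estimated correlation). MRPL11 fell by 3.38 on the log2 scale. MRPS25 had 0.39 ± 0.14 (adjusted p = 0.0277) and did not pass without day 0 replicate 2 (0.0729), day 0 replicate 3 (0.114) or day 30 replicate 3 (0.0761). Counts of both lists were the same when adjusted over the list alone.

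MYC proteins, transcription factors that activate ribosome biogenesis genes, and their partners moved in both directions. MYCN went from 61 ± 7.27 to 7.06 ± 1.08 CPM, a log2 change of −3.08 ± 0.16, and MYC from 67 ± 7.22 to 39.2 ± 1.05 CPM, a log2 change of −0.77 ± 0.12. MXD1, a MAX-binding repressor that opposes MYC, rose from 9.29 to 45.1 CPM, a log2 change of 2.28 ± 0.18. In the family 4 of 10 fell and 5 rose, also when adjusted over the list alone (median 0.30, camera adjusted p = 0.832).

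Stem cell and cell division genes fell. All 22 tested pluripotency genes fell, with a median of −7.51, or −6.61 with the 2 genes at 0 on day 30 set to their bounds (camera adjusted p = 6.59e-10; adjusted p = 0.0632 with an estimated correlation). Those 2 passed the filter through their day 0 reads alone, so they could only fall. LIN28A, an RNA-binding protein of pluripotent cells, went from 1550 ± 173 to 6.68 ± 0.987 CPM. POU5F1 held 2405 counts on day 0 and 3 on day 30, a ratio of 991 (95% counting interval 339 to 4810). Its fitted log2 change of −9.78 became −12.78 without day 30 replicate 1 and −8.94 without day 30 replicate 2, and it lies in the MHC region, where most genes held almost no reads. NANOG had −8.98 ± 0.45, −11.09 without day 30 replicate 1 and −8.11 without day 30 replicate 2. SOX2, which neural cells also express, fell by 1.80. The non-coding RNA HPAT5 was at least 912-fold lower on day 30, when it had no reads. All 28 cell cycle genes fell (median −5.03, camera adjusted p = 3.86e-12; adjusted p = 0.175 with an estimated correlation). CDK1, the mitotic kinase, went from 164 ± 14 to 1.66 ± 0.634 CPM, and the proliferation marker MKI67 from 297 ± 36 to 10.3 ± 5.78 CPM.

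Neuronal genes and most tested hypothalamic genes rose. All 24 tested pan-neuronal genes rose (median 5.48, camera adjusted p = 7.9e-10; adjusted p = 0.175 with an estimated correlation). MAP2, a dendritic microtubule protein, went from 10.1 ± 2.23 to 2690 ± 278 CPM, STMN2 from 6.02 to 1250 ± 215 CPM and TUBB3 from 66 ± 7.6 to 362 ± 62.2 CPM. Of 35 listed hypothalamic and arcuate genes 22 could be tested, of which 17 rose and 2 fell, or 18 and 2 adjusted over the list alone. Their median was 7.43, or 7.02 with the 5 genes at 0 on day 0 set to their bounds (camera adjusted p = 3.12e-05; adjusted p = 0.175 with an estimated correlation). Those 5 passed the filter through their day 30 reads alone, so they could only rise. The counts, median and camera p of this list therefore reflect the filter in part. POMC (chromosome 2, 25160853 to 25168903), the precursor of melanocortin peptides made by arcuate neurons, rose from 1.02 ± 0.241 to 1520 ± 358 CPM, a log2 change of 10.54 ± 0.29. SST, the peptide somatostatin, rose from 0.384 to 2090 ± 562 CPM. NKX2-1, a transcription factor of the ventral hypothalamus, was at least 408-fold higher, at 0 on day 0 and 51.6 ± 7.23 CPM on day 30. LHX6, a transcription factor of ventral forebrain neurons, fell by 2.98 (−4.94 without day 30 replicate 2). The arcuate peptide genes NPY, AGRP and GHRH, chosen after their values were seen, held 19, 6 and 15 counts over the day 30 libraries and 0 on day 0, and were not tested. The largest rises outside the lists were UTS2, the precursor of the peptide urotensin, which was at least 3570-fold higher (454 ± 65.6 CPM on day 30), and ISLR2, TNR and the glycine receptor subunit GLRA2, at least 1570-fold, 796-fold and 792-fold higher. All 4 were at 0 on day 0.

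**Figure D4:**
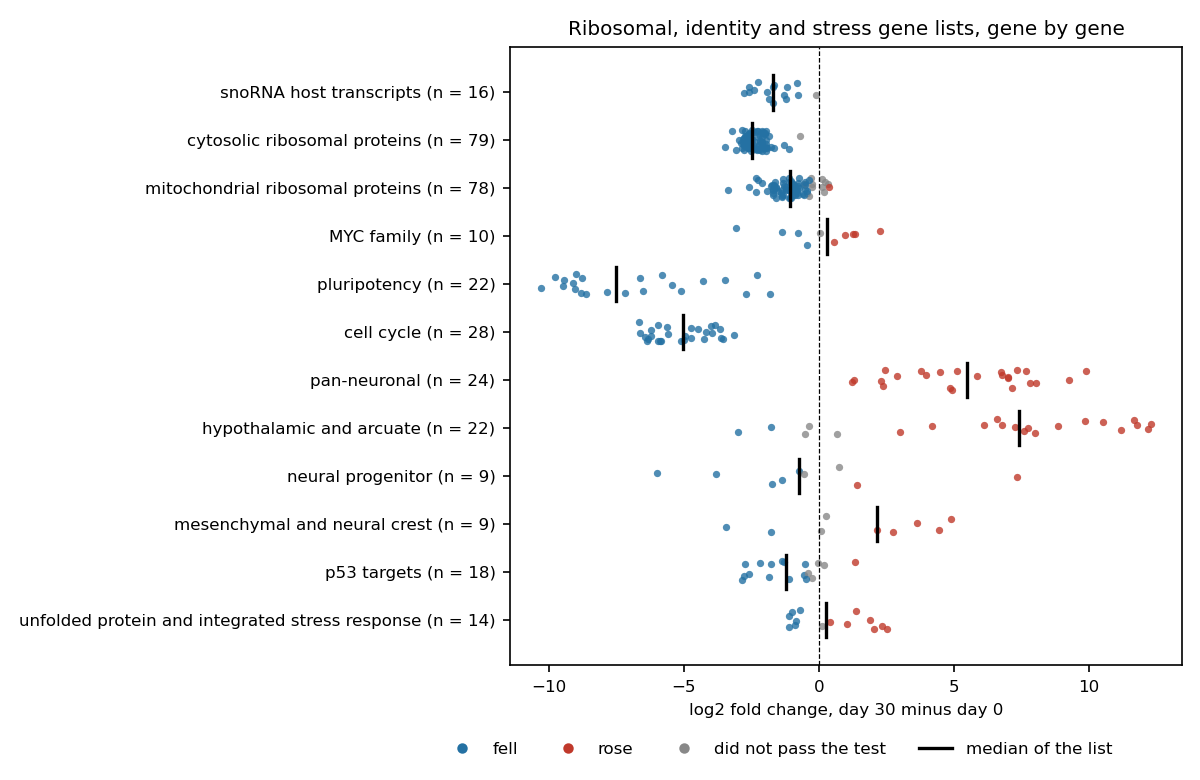
Log2 fold change, day 30 minus day 0, of each tested member of some of the other lists. These are snoRNA host transcripts, cytosolic and mitochondrial ribosomal proteins, the MYC family, pluripotency, cell cycle, pan-neuronal, hypothalamic and arcuate, neural progenitor, mesenchymal and neural crest, p53 targets, and the unfolded protein and integrated stress response. Each gene is 1 point, blue for genes that fell, red for genes that rose and grey for genes that did not pass the test. A black bar marks each list's median. Medians were −7.51 for pluripotency, −5.03 for the cell cycle, 5.48 for pan-neuronal genes and 7.43 for hypothalamic and arcuate genes.

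Markers of other neural cell types went both ways. Of 9 tested neural progenitor genes, 5 fell and 2 rose, or 5 and 3 adjusted over the list alone (median −0.74, camera adjusted p = 0.445). PROM1 fell by 5.99 on the log2 scale (−6.80 without day 30 replicate 2). SOX1, an early neural transcription factor, held 2 counts on day 0 and 488 on day 30, a ratio of 197 (95% counting interval 54.3 to 1630), and its fitted value of 7.35 was 10.16 without day 0 replicate 3. Of 6 tested astroglial genes, from 10 listed, 4 fell and 2 rose (median −2.43, camera adjusted p = 0.481). The direction by fry was up although the median was below 0 (adjusted p = 0.896). The glutamate transporters parted, as SLC1A2 rose from 7.27 to 231 ± 9.22 CPM and SLC1A3 fell by 3.32 (−4.12 without day 30 replicate 3). Of 7 tested oligodendroglial genes, from 9 listed, 3 fell and 1 rose (median −0.79, camera adjusted p = 0.474). The one that rose was NKX2-2, a ventral neural tube transcription factor, at least 71.2-fold higher. None of the 15 HOX genes of hindbrain and spinal cord could be tested, as no member had more than 4 counts in a library. Counts of the astroglial and oligodendroglial lists, and of the lists that follow here, were the same when adjusted over the list alone.

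The lists that follow speak only for their tested members, as listed genes with too few reads were not tested. In the telencephalon list of 8 genes, 3 of 4 tested fell and 1 rose (median −2.08, camera adjusted p = 0.275, fry adjusted p = 0.00383). For choroid plexus and ependyma, with 8 genes listed, 2 of 3 tested fell and 1 rose (median −3.24, camera adjusted p = 0.474, fry adjusted p = 0.00294). OTX2, a factor of stem cells and forebrain, fell by 7.23. All 3 tested endoderm genes, of 10 listed, fell (median −6.36, camera adjusted p = 0.0146, adjusted p = 0.175 with an estimated correlation). With DESeq2 statistics the adjusted p of that list was 0.0532, and over all alternatives it ranged from 1.78e-05 to 0.175. CER1, a secreted NODAL antagonist, fell by 7.03 (−7.62 without day 30 replicate 2). Both tested endothelial genes, of 8 listed, fell (median −5.84, camera adjusted p = 0.0351, adjusted p = 0.243 with an estimated correlation). Among them was the receptor TEK, from 40.3 to 0.578 CPM. TEK and CER1 held 17 and 6 counts over the day 30 libraries, so their day 0 reads carried them past the filter. The endothelial list had an adjusted p of 0.0513 with the stricter filter on low counts and ranged from 3.86e-05 to 0.243 over all alternatives.

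Mesenchymal genes set 1 library apart. Of 9 tested mesenchymal and neural crest genes, 5 rose and 2 fell (median 2.15, camera adjusted p = 0.832), and collagen mRNAs were highest in day 30 replicate 3. COL1A1 was at 82.7, 245 and 1720 CPM in day 30 replicates 1, 2 and 3, and COL3A1 at 16.1, 71.4 and 853 CPM. The fibrillar collagen COL3A1 had a log2 change of 4.90 ± 1.34 (adjusted p = 0.00632), which was 2.11 (adjusted p = 0.0333) without day 30 replicate 3, 6.47 without day 0 replicate 2, and 3.99 by limma-voom, where it did not pass (adjusted p = 0.0778). COL1A1 at 2.74, COL1A2 at 2.15 and POSTN at 3.62, chosen after their values were seen, did not pass without day 30 replicate 3, at 0.71, 0.27 and 1.41. COL1A2 did not pass without any 1 of the day 0 libraries either (adjusted p = 0.11, 0.0676 and 0.0814). PRRX1, the fifth, also chosen after its value was seen, had 4.47, with 3.84, 9.33 and 3.83 when day 0 replicate 1, 2 or 3 was left out. TAGLN, a smooth muscle actin-binding protein, fell from 596 ± 129 to 55.5 ± 33.7 CPM. Without day 30 replicate 3, 2 genes of the list rose and 4 fell, genes higher at day 30 numbered 7293, genes lower at day 30 numbered 6697, and 157 factors were lower and 5 higher.

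**Figure D5:**
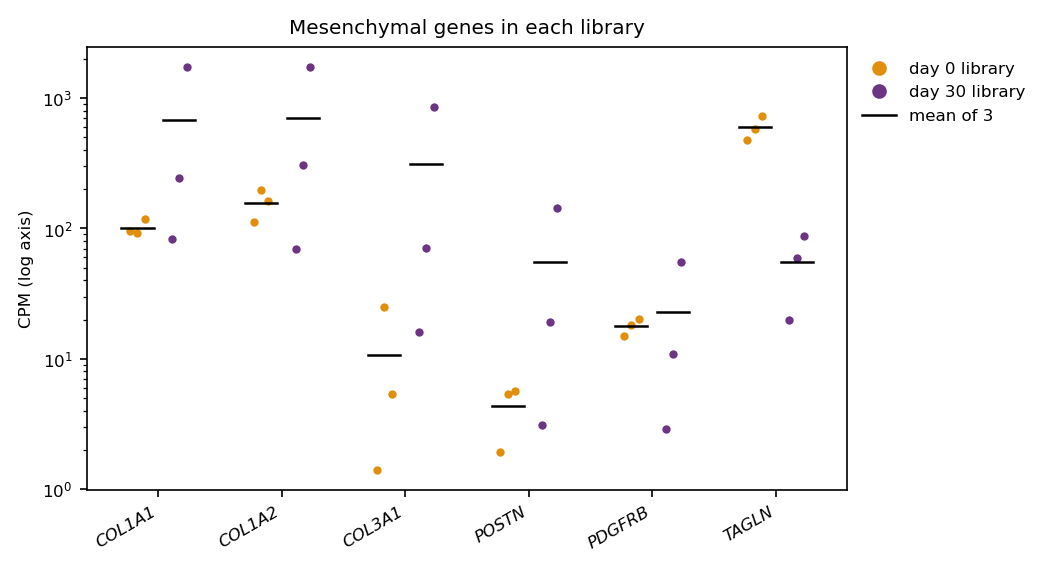
CPM on a log axis in each library for COL1A1, COL1A2, COL3A1, POSTN, PDGFRB and TAGLN, with 1 point per library. Day 30 replicate 3 held 1720 CPM of COL1A1, against 82.7 and 245 CPM in the other day 30 libraries.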

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

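The subtraction of shared small RNA reads was chosen after the result was seen, and the other alternatives were planned. Genes higher on day 30 numbered from 5302 with the stricter filter to 9147 with no filter, and genes lower from 4451 at 2-fold or more to 7692 with no filter. Factors lower numbered 156 to 164 and factors higher 4 to 5 over the alternatives run for them, which held no minimum fold, and 109 factors were lower by 2-fold or more. With 1 library left out, 616 to 1059 calls were lost, 0 changed sign, and 2 to 6 factor calls were lost. The median of all genes was 0.06 to 0.17 over the scalings, the median of the factors −1.23 to −1.11, and the length trend left it at −1.27. Of 594 set tests under alternatives 553 kept direction and side of the threshold, as did 1340 of 1365 values of named genes and 82 of 85 other results. In simulated data 12.3% of genes changed 1.5-fold were recovered, and depth was not separated there from the number of libraries or their spread. Only 200 genes were changed there, whereas 76.6% of genes passed in the real data, so the adjusted threshold was stricter in the simulation. The 12.3% is thus no estimate of what the reported comparison recovered. DESeq2 was not run for small against large subunit factors, since it gives no test of that difference. Where a result changed, the cause was not tested, except that the stricter filter tests fewer genes.

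With the correlation estimated per list, camera gave p = 0.0656 for all factors (range over alternatives 3.12e-25 to 0.0656), which was not adjusted over the lists. The adjusted p was 0.0632 for pluripotency, 0.175 for UtpB, large subunit assembly, the exosome, abundant nucleolar proteins, processing snoRNAs, snoRNA hosts, cell cycle, pan-neuronal, hypothalamic and endoderm lists, 0.212 for RNase MRP and RNA polymerase I, 0.243 for UtpA, other processome factors, H/ACA and endothelial lists, 0.252 for the U3 snoRNP, 0.272 for cytosolic and mitochondrial ribosomal proteins and p53 targets, 0.299 for late 40S maturation and 0.349 for the Mpp10 module. These were the highest values of each list over its alternatives.

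With the stricter filter the adjusted p was 0.0518 for the Mpp10 module, 0.0763 for processing snoRNAs, 0.0513 for endothelial genes and 0.818 for floor plate genes, whose direction turned. With DESeq2 statistics it was 0.0532 for UtpB, 0.121 for the Mpp10 module, 0.0531 for RNase MRP, 0.0595 for processing snoRNAs, 0.0532 for endoderm and 0.678 for astroglia, whose direction turned. With fry it was 0.000389 for floor plate genes (range 0.000389 to 0.818), 0.00294 for choroid (0.00294 to 0.905), 0.00383 for telencephalon (0.00383 to 0.556), 0.0334 for the unfolded protein response (0.0334 to 0.93) and 0.896 for astroglia (0.178 to 0.896), with direction up.

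Small minus large subunit factors differed by 0.10 with no filter and by 0.16 with small RNA reads subtracted, and both then passed by fry, which the reported difference of 0.11 did not. Over the alternatives the difference was 0.08 to 0.16. WDR74 went to −1.58 with small RNA reads subtracted. With the stricter filter DDX52 was 0.09, TAF1A 0.10 and TENT4B 0.05. With total counts only they were 0.07, 0.07 and 0.02, and TAF1A was 0.00 with upper-quartile normalization. With 1 library left out UTP23 was −0.11 to 0.18, DDX52 −0.19 to 0.24, TAF1A −0.17 to 0.08, and the adjusted p of the mesenchymal list 0.42 to 0.924, with its direction turned without day 0 replicate 1 or day 30 replicate 3.

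The labels do not pair the replicate numbers. With the number as a block, genes higher at day 30 numbered 6921 and genes lower at day 30 numbered 6415, with 159 factors lower and 5 higher. Small minus large subunit factors then differed by 0.11 and passed by fry. DIS3 (adjusted p = 0.0539) and MRPS25 (adjusted p = 0.054) did not pass. In the pairing check, deviations from the group mean correlated across genes with r of 0.12, −0.02 and −0.06 between libraries of the same number, and with up to 0.24 between others.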

Other observations

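Of the tests below, those on WDR74, on gene length, on scaling and on the MHC region were chosen after the result was seen, and the others before. Genes of the sonic hedgehog response went in both directions. Per the labels' protocols, sonic hedgehog and purmorphamine were in the medium during differentiation, and activity of the pathway was not measured. Of 8 tested floor plate and sonic hedgehog response genes, 6 rose and 2 fell, also when adjusted over the list alone (median 2.30, camera adjusted p = 0.15, fry adjusted p = 0.000389). With the stricter filter on low counts, which tests fewer of them, the direction turned (median −0.63, adjusted p = 0.818), and the adjusted p ranged from 0.000389 to 0.818 over all alternatives. GLI1, a transcription factor and target of the pathway, fell by 3.91 on the log2 scale, and by 4.84 without day 30 replicate 3. The pathway's receptor PTCH1, also a target and chosen after its value was seen, rose from 21.7 to 76.9 CPM, a log2 change of 1.82.

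Among 18 tested p53 targets 13 fell and 1 rose, also when adjusted over the list alone (median −1.20, camera adjusted p = 0.00384; adjusted p = 0.272 with an estimated correlation). FDXR, a mitochondrial reductase, fell by 2.86, and the antiproliferative gene BTG2 rose by 1.34. In the unfolded protein and integrated stress response, 7 of 14 rose and 6 fell, also when adjusted over the list alone (median 0.26, camera adjusted p = 0.764, fry adjusted p = 0.0334). DDIT3, the stress-induced factor CHOP, rose from 4.89 to 28.2 CPM, a log2 change of 2.52, and PDIA4, a chaperone of the endoplasmic reticulum, fell by 1.11. Of genes for variant ribosomal proteins, 3 chosen after their values were seen fell, and others were not examined as a group. RPL39L went from 55.8 ± 8.22 to 3.16 ± 0.434 CPM (SD, n = 3), RPL22L1 from 77.4 ± 3.31 to 5.61 ± 0.601 CPM and RPS27L from 117 ± 25.7 to 35.1 ± 3.34 CPM. Their log2 changes were −4.17, −3.76 and −1.73, with −2.76 for RPL39 and −2.05 for RPL22.

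WDR74 was listed as higher on day 30, unlike most large subunit factors. Reads of the U2 small nuclear RNA gene RNU2-2P, which lies within it on the same strand, may have been counted in it. RNU2-2P rose from 30 ± 3.36 to 145 ± 33.6 CPM (log2 change 2.28 ± 0.18), and after its counts were subtracted WDR74 had −1.58 ± 0.14 (adjusted p = 1.84e-06). Several counts of both genes were fractional, yet WDR74 minus RNU2-2P was a whole number in each of the 6 libraries, so the fractional reads of RNU2-2P were counted in WDR74 as well. The remaining reads were 43.6, 51.6 and 51.9 CPM in the day 0 libraries and 15.6, 18.3 and 14.7 CPM in the day 30 libraries, so a fall of WDR74 mRNA with differentiation is the hypothesis that these values leave.

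Cytosolic ribosomal protein mRNAs had a median log2 change of −2.46. The upper quartile of the list stayed at −2.13 after the trend on exon length was removed. That length joined all annotated exons of a gene (median 3130 bases for the list) and can differ from the length of its mRNA. A bias by mRNA length therefore stays open. The highest median among the scalings run was −2.37, so the fall did not depend on the choice among them. All of them are relative, so a difference in RNA per cell between the days could not be judged. Reads moved to pseudogenes were argued against, as ribosomal protein genes and their pseudogenes summed fell by 2.32 ± 0.11 (SE). A candidate explanation is a fall of mRNAs with a 5′ terminal oligopyrimidine motif as a class: in a list of other such mRNAs 14 of 14 tested fell (median −1.88), against 13 of 17 for translation factors without it (median −0.84), a difference of −0.89 in mean log2 change (exact permutation p = 0.1, the smallest possible), which passed by fry. The abundant nucleolar proteins, a list not chosen by this motif, had a median of −2.18, and all processing factors had −1.21. The comparison thus does not set motif mRNAs apart from other genes of ribosome production. A shared change of this class with differentiation is a hypothesis, which leaves transcription and stability untold.

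Genes used by every cell, such as RPS18 and the factors WDR46, RPP21 and POLR1H, held almost no reads on either day, and these lie in the MHC region of chromosome 6 (30058899 to 33323016), for which hg38 carries alternate haplotype sequences. Of 25 housekeeping genes there, 23 (92%) had 10 or fewer reads in every library, against 2 of 15 (13.3%) beside the region. The 25 include 5 genes of the gene lists whose low counts prompted the test, and without them 18 of 20 (90%) were as low. This is consistent with reads that match several haplotype sequences having been left uncounted, in which case these genes may be expressed at levels that the table does not show. The factors PWP2, AATF, DDX24, PARN and RRN3 were as low but lie outside the region, so their low counts stay open, as untested, and no biological explanation was tested.

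The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. All splits but the real one mix the days, which puts the difference between the days into the spread within their groups. Few calls were therefore likely in them in any case, and their counts do not weigh against chance. Genes higher numbered 7186 for the real split and at most 0 for the others by edgeR, genes lower 6641 and 0, factors lower 163 and 0, and factors higher 5 and 0, so that 1 split, the real one, gave as many in each case. At an unadjusted p under 0.05 the other splits gave at most 53 genes higher, 32 lower and 0 factors by edgeR. For the camera test of all factors, 2 of the 10 splits had a p as small as the real one, 3.21e-17, and the smallest p of the others was 2.29e-17.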
